A study of Oryza sativa with 3 samples.

How the data were processed

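The data are 3 two-colour Agilent oligonucleotide arrays of rice roots. Per the labels' protocols, total RNA was extracted with a column kit with DNase treatment and a further clean-up, amplified and labelled during in vitro transcription with a linear amplification kit, with Cy5 for roots exposed to Cr(VI) and Cy3 for roots in water. Dyes ran the same way on every array. The labels give the 3 arrays as biological replicates. The ratio within an array holds the pairing of the treated and the control sample.

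Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, and the deposited intensity columns hold the mean brightness of each spot and the median of its local background. Processed intensities, per the file headers, are background-subtracted, detrended and dye-normalized within the array. The deposited scanner files also hold log10 ratios of the processed red over green signals. Other columns, per the file headers, are flags of 0 or 1 per spot for signal well above background, saturation and outliers. The authors' deposited value table holds log2 ratios of Cy5 over Cy3. Their base and direction were settled by setting them against the log2 of the ratios in the scanner files: 95.9%, 97.4% and 92.0% of 42416 probes lay within 0.01 on the 3 arrays, in that base and direction. The medians of its 3 columns were -0.10, -0.15 and -0.15, so it is not centred, and how spots of a probe were joined is not given in the sources used here.

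From the scanner files, mean signals were background-corrected by normexp with an offset of 50, using the median local background, and log2 ratios were normalized by loess within each array in limma 3.58.1 (R 4.3.3 and version 1.17.8 of data.table). The 2007 control spots had weight 0 in loess and were left out after it. Outlier spots, of which the arrays had 24, 15 and 64, were left out, and spots of a probe were averaged. Of 42418 rice probes, 35503 were tested, having a value on all 3 arrays and being well above background on all 3 in at least 1 channel. For the 6850 genes with more than 1 tested probe, the probe of the highest mean intensity stood for the gene. This gave 24864 features, of which 24633 are genes with a locus identifier and 231 are miRNA precursor or other probes without one. Of 29689 locus genes on the array, 5056 were left out by the filter or an outlier spot. Gene names are those of the array design and can be old. None of its locus identifiers or accessions matched the reference table given (0 of the 29689 loci), so the design's names were kept. The files give a chromosome by locus but no positions, and a genome build is not given in the sources used here. A lower bound on a fold sets the bright channel's mean against the higher of the lowest signal well above background and the probe's own signal, after loess and Aquantile, and it is open to dye bias. Where the probe's own signal is the higher, the value is the measured ratio and not a minimum.

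Each feature's 3 log2 ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The median SD over the arrays was 0.092 and the prior degrees of freedom 1.95. Before the data were examined, 38 gene lists were fixed by patterns on the gene descriptions. The 36 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and the other 2 were only counted. Patterns also took in genes of other functions, which the results name where they lead a list. They also missed genes whose descriptions use other words, so a list need not hold the whole of a family. The rule for named genes, also fixed before the data were examined, took 3 kinds. The first is the 10 highest and 10 lowest called log2 ratios with the same sign on all arrays, well above background in both channels and a described function. The second is the 2 highest and 2 lowest called members of each list, and the third the 3 largest bounds in each direction. That gave 162 genes, of which the results print up to 4 per list.

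Alternatives changed the background correction, the signals, the normalization within and between arrays, the filter on dim probes, the joining of probes, the outlier spots, the moderation, the array weights, the pairing, the slide as a block, the replicates and the set test, and used the authors' table. The steps were tested on simulated data, 10 draws of 3 arrays with 24864 features, the real dye curves and the real spread, comparing Cr(VI) with water. Of 500 changed genes per size, 50.6% were recovered at 1.5-fold, 71.6% at 2-fold, 89.0% at 4-fold and 94.2% at 8-fold. Between 2 and 8 of 24634 unchanged features were called in a draw. Each draw changed only 200 genes and a list of 30, far fewer than were called in the real data. The adjusted threshold was therefore stricter in the draws. These recoveries and false calls do not measure those of the real fit. Of 2000 random lists of 50 unchanged genes, 1.10% had a camera p under 0.05 and 0 an adjusted one. Simulated noise was independent between genes, so these lists do not measure the effect of correlated genes. With 3 arrays and no dye swap, precision is limited by the number of arrays.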

Results

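The study asked how the transcripts of rice roots changed after exposure to an excess of hexavalent chromium, Cr(VI), a toxic oxyanion of the metal. Roots came from 5-day-old seedlings of the cultivar TN-67, and 3 two-colour oligonucleotide arrays each carried RNA of roots exposed to 200 µM Cr(VI), labelled with Cy5, against RNA of roots kept in water, labelled with Cy3. The labels name the arrays as 3 biological replicates, and the length of the exposure is not given in the sources used here. Each array held 43144 rice spots, of which 83.0% to 91.7% were well above background in the Cr(VI) channel and 81.1% to 90.05% in the water channel. No rice spot was saturated in either channel. The number of arrays limits the precision of every value below. All log2 ratios are Cr(VI) over water, given as the mean of n = 3 arrays ± the moderated SE of the limma fit. That SE draws on the spread of all features, so it is not the SE of a gene's 3 arrays alone. It can be smaller than that SE where a gene's arrays differ widely. A gene is said to have risen or fallen only where its adjusted p in the limma fit passed 0.05.

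The large changes in root transcripts after Cr(VI) were mostly increases. The RING zinc finger gene Os02g0559800 had a log2 ratio of 6.05 ± 0.073, the highest among genes with a described function, and a cytochrome P450 gene of the CYP72A5 type, Os01g0627800, followed at 5.85 ± 0.050. Among the other strongly raised genes were the UDP-glucosyltransferase genes Os04g0206600 at 5.71 ± 0.17 and Os05g0527000 at 5.14 ± 0.17, whose enzyme family attaches sugars to small molecules. The SUI1-type translation initiation factor gene Os04g0627900 stood at 5.65 ± 0.055, the NAC transcription factor gene Os01g0816100 at 5.30 ± 0.13 and the transcriptional coactivator gene Os06g0592500 at 5.13 ± 0.12. Serine acetyltransferase, Os03g0196600, which makes the precursor of cysteine, rose by 5.12 ± 0.048, the gene described as a regulator of gene silencing, Os01g0955100, by 4.97 ± 0.12, and the aldo/keto reductase gene Os04g0339400 by 4.87 ± 0.16. Falls were smaller. The lowest mean log2 ratio among genes of described function was that of the pathogenesis-related gene PR-1a, Os02g0786900, at -2.11 ± 0.45, with -2.90, -2.60 and -0.85 on the 3 arrays. The Avr9/Cf-9 rapidly elicited gene Os03g0179400 stood at -2.06 ± 0.29, a glyoxal oxidase gene, Os03g0258900, at -2.06 ± 0.12, and a protein kinase gene, Os01g0935800, at -1.99 ± 0.13. Further falls were those of the UDP-glucosyltransferase gene Os02g0206700 at -1.76 ± 0.13, the NAM/CUC2-like gene Os04g0515900 at -1.76 ± 0.094, the probenazole-inducible gene PBZ1, Os12g0555500, at -1.74 ± 0.41, and the GDSL lipase gene Os03g0310000 at -1.74 ± 0.20. The auxin conjugate hydrolase gene ILL5, Os01g0706900, which releases free auxin, stood at -1.72 ± 0.10 and a beta-amylase gene, Os10g0465700, at -1.72 ± 0.26. The 20 genes had adjusted p-values between 0.000136 and 0.0313 in the limma fit. The calls of PR-1a, PBZ1, Os03g0179400 and Os10g0465700 were each lost when replicate 2 was left out, and that of PR-1a also without replicate 1 and that of PBZ1 also without replicate 3.

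**Figure D1:**
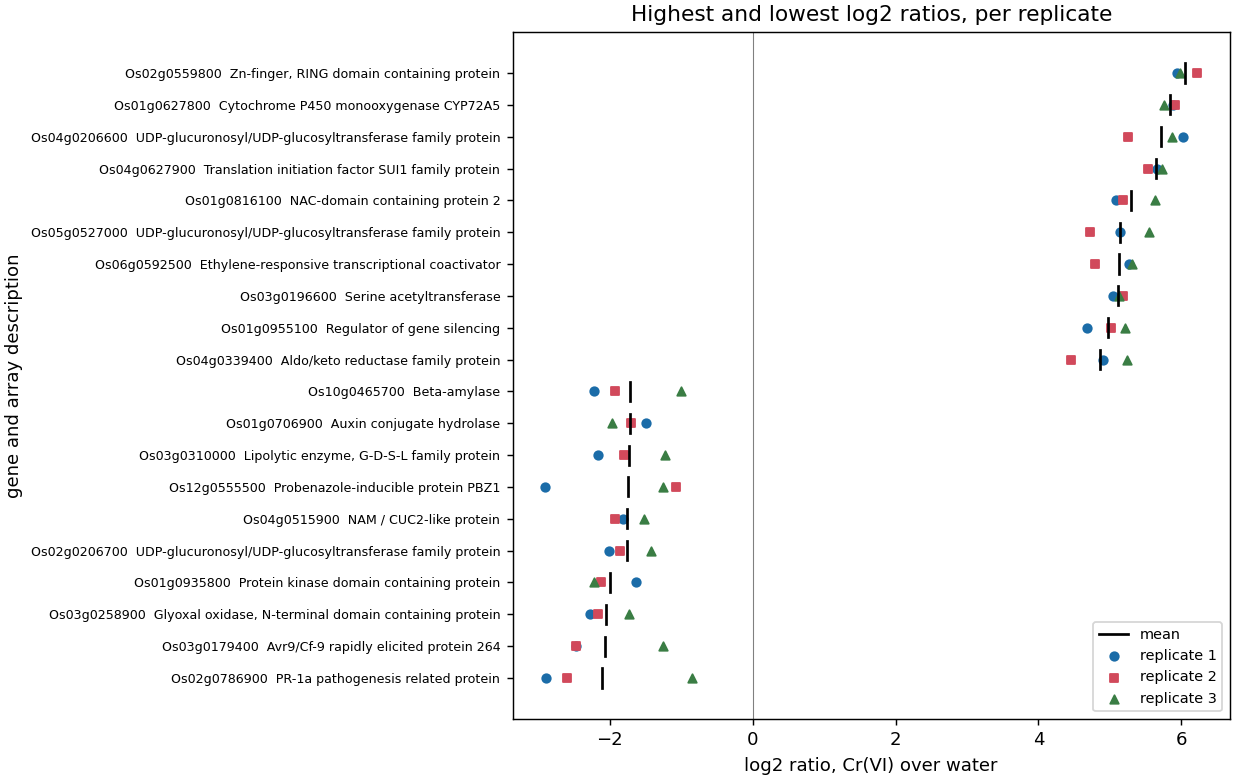
Log2 ratio of Cr(VI) over water for the 10 highest and 10 lowest genes of described function, 1 symbol per array and a bar at the mean of 3 arrays. The 10 rises lie between 4.87 and 6.05 and the 10 falls between -2.11 and -1.72, and the replicates of PR-1a and PBZ1 spread most among the falls.

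Of 24864 tested features, 7008 were higher and 5781 were lower after Cr(VI) by limma's moderated test with Benjamini-Hochberg adjustment, together 51.4% of all tested, against 3373 and 1507 without replicate 2 and 4477 and 2750 without replicate 1, each with 1 array fewer in the fit. All 12789 called features had the same sign on all 3 arrays. With 3 arrays a call at this threshold requires that, so it is no separate evidence that the replicates agree. At least a 2-fold change was reached by 1805 higher and 276 lower features (1545 and 166 without replicate 2, 2185 and 473 with Agilent's processed signals), so 86.7% of these larger calls were higher, while the calls of any size were split more evenly, with 54.8% higher. A 4-fold limit left 588 higher and 8 lower calls, and an 8-fold limit 213 higher and 0 lower. The 8512 calls under 1.5-fold made up 66.6% of all calls. No functional description was given for 616 of the 2-fold higher and 124 of the 2-fold lower calls. The Cr(VI) sample carried Cy5 on all 3 arrays, so a dye effect of a single gene and its response to Cr(VI) cannot be told apart by the test. Of the calls from the authors' deposited value table, which is not centred and has a median of -0.13 over tested features, 34.9% were higher (72.1% at 2-fold, 1898 against 733), and of the fewer calls left after aligning the arrays to one another on their external control RNAs with their common level kept, chosen after seeing the data, 78.0% were.

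**Figure D2:**
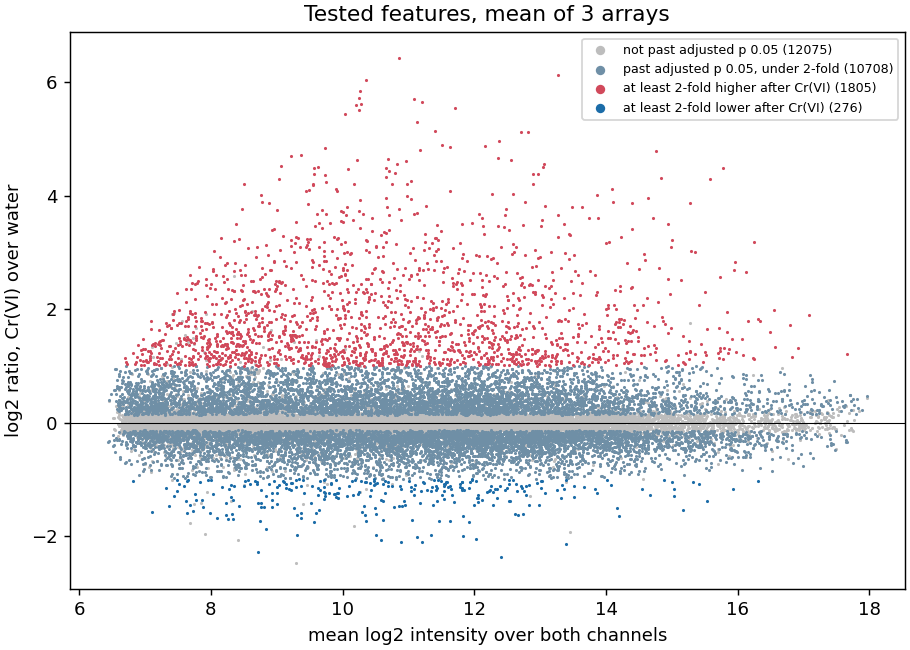
Log2 ratio of Cr(VI) over water against mean log2 intensity for the 24864 tested features, each point the mean of 3 arrays. The 1805 features at least 2-fold higher reach a log2 ratio of 6.43, while the 276 at least 2-fold lower go down to -2.37.

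In the lists of glutathione S-transferases, of sulfate uptake and assimilation and of antioxidant enzymes, more genes rose than fell. Of 65 tested glutathione S-transferase genes, whose enzymes join glutathione to reactive compounds, 39 rose, 3 fell and 23 did not pass, with the same counts adjusted over the list alone. GST6, Os09g0367700, had a log2 ratio of 4.29 ± 0.13 and the GSTU31-type gene Os10g0481300 one of 4.20 ± 0.17, while the lowest called member, Os01g0371200, stood at -0.28 ± 0.041, a call lost without replicate 1 or 2. The list median was 0.43, and limma's camera put the list above the other genes with an adjusted p of 4.75e-07, against an adjusted p of 0.582 with an estimated correlation. With 3 arrays the estimated correlation and its test rest on few residual degrees of freedom, so that test has little power for any list. Among 30 genes of sulfate uptake and assimilation, 17 rose, 1 fell and 12 did not pass, against 18 and 3 that passed adjusted over the list alone. Beside serine acetyltransferase, a cysteine synthase gene, Os02g0222100, rose by 3.47 ± 0.12, and the member that fell was a sulfate transporter gene, Os04g0652400, at -0.42 ± 0.10, a call lost without replicate 2. The list had a median of 0.34 and an adjusted p of 0.00427 in limma's camera, against an adjusted p of 0.582 with an estimated correlation. For 48 genes of the ascorbate-glutathione cycle and other antioxidant enzymes, 19 rose, 4 fell and 25 did not pass, with the same counts adjusted over the list alone. Peroxiredoxin 6, Os07g0638300, rose by 2.30 ± 0.29, with 3.43 as its highest probe value, and monodehydroascorbate reductase, Os08g0557600, which regenerates ascorbate, by 1.86 ± 0.18, while an iron superoxide dismutase gene, Os06g0115400, fell to -0.40 ± 0.043, a call lost without replicate 2. The lowest called member was glutathione synthetase, Os12g0263000, at -0.42 ± 0.089, with -0.23, -0.41 and -0.63 on the 3 arrays. Its highest probe value was -0.14. This list had an adjusted p of 0.0416 in limma's camera and an adjusted p of 0.689 with an estimated correlation, and the call was also lost without replicate 3 and with array weights.

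Other enzyme and transporter families held strongly raised genes without a shift of the whole list in limma's camera. At least 2-fold higher and lower were 36 and 7 of 173 cytochrome P450 genes and 26 and 7 of 122 UDP-glycosyltransferase genes. The counts were 15 and 2 of 79 ABC transporter genes, 5 and 1 of 38 MATE genes and 18 and 4 of 102 metal genes. For thioredoxins and glutaredoxins they were 7 and 0 of 76, and for class III peroxidases 6 and 5 of 116. Over all 24864 features they were 1805 and 276, and these shares were not tested. Of 173 cytochrome P450 genes, 59 rose, 27 fell and 87 did not pass, against 57 and 27 that passed adjusted over the list alone. The P450 pattern missed 24 tested genes described as E-class P450, group I, of which 10 rose and 2 fell. Beside Os01g0627800, the P450 gene Os07g0418500 rose by 4.52 ± 0.062, and CYP99A1, Os04g0178400, stood at -1.62 ± 0.28, a call lost without replicate 1 or 2; the list had an adjusted p of 0.169 in limma's camera. Among 122 UDP-glycosyltransferase genes, 45 rose, 35 fell and 42 did not pass, against 46 and 37 that passed adjusted over the list alone, with a lowest log2 ratio after Os02g0206700 of -1.70 ± 0.15 for Os07g0201500, a list median of -0.00011 and an adjusted p of 0.683 in limma's camera. For 79 ABC transporter genes, 31 rose, 14 fell and 34 did not pass, against 35 and 15 that passed adjusted over the list alone. The PDR3 gene Os01g0609300 rose by 2.89 ± 0.047, and the ABC transporter gene Os09g0250800 fell to -1.58 ± 0.15 (adjusted p of 0.104 for the list in limma's camera). Of 38 MATE efflux genes, 10 rose, 7 fell and 21 did not pass, with the same counts adjusted over the list alone, and Os10g0345100 reached 4.62 ± 0.13 and Os04g0373400 3.52 ± 0.064, with an adjusted p of 0.561 for the list in limma's camera. In the list of 102 genes of metal chelation and transport, 33 rose, 22 fell and 47 did not pass, against 33 and 23 that passed adjusted over the list alone. Os04g0469000, of the heavy metal transport and detoxification domain family, rose by 2.60 ± 0.048 and Os07g0671400, of the same family, fell to -1.23 ± 0.10; limma's camera gave the list an adjusted p of 0.573. Thioredoxins and glutaredoxins numbered 76, of which 23 rose, 13 fell and 40 did not pass, with the same counts adjusted over the list alone; the glutaredoxin genes Os01g0241400 and Os02g0618100 rose by 3.68 ± 0.052 and 3.39 ± 0.043, and the adjusted p of the list was 0.513 in limma's camera. Class III peroxidases numbered 116, of which 25 rose, 42 fell and 49 did not pass, against 26 and 43 that passed adjusted over the list alone. Os04g0688300 rose by 2.52 ± 0.23 and Os07g0677300 fell to -1.27 ± 0.16, with an adjusted p of 0.144 for the list in limma's camera.

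Nutrient transport gave mixed counts. Of 36 genes of nitrate and ammonium uptake and assimilation, 13 rose, 5 fell and 18 did not pass, with the same counts adjusted over the list alone. Nitrate reductase, Os02g0770800, rose by 4.01 ± 0.12, the gene described as a symbiotic ammonium transporter, Os09g0455300, rose by 2.74 ± 0.15, and the ammonium transporter gene Os02g0550800 fell to -1.04 ± 0.042; the list had an adjusted p of 0.545 in limma's camera. Among 18 phosphate transport and SPX genes, 7 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone. The SPX gene Os02g0202200 rose by 1.42 ± 0.10 and the phosphate transporter gene Os03g0150600 by 1.30 ± 0.048, while the SPX gene Os10g0392600 fell to -0.82 ± 0.039 (adjusted p of 0.573 in limma's camera). For 18 aquaporins, 6 rose, 5 fell and 7 did not pass, with the same counts adjusted over the list alone, and none reached 2-fold. The tonoplast gene Os04g0527900 rose by 0.80 ± 0.061 and the plasma membrane gene Os07g0448200 fell to -0.50 ± 0.045. The list of aquaporins had an adjusted p of 0.869 in limma's camera.

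In all 5 transcription factor lists more genes rose than fell, and 4 of the lists passed in limma's camera, none of them with an estimated correlation (adjusted p of at least 0.582). Of 62 WRKY genes, 41 rose, 6 fell and 15 did not pass, against 42 and 8 that passed adjusted over the list alone. WRKY28, Os06g0649000, rose by 4.20 ± 0.075, and WRKY71, Os02g0181300, rose by 3.60 ± 0.22 by its brightest probe, with 1.55 as its lowest probe value. The lowest called WRKY gene, Os04g0597300, stood at -0.61 ± 0.067. The list median was 0.44, with an adjusted p of 3.98e-05 in limma's camera and an adjusted p of 0.582 with an estimated correlation. Among 22 heat shock factor genes, 14 rose, 0 fell and 8 did not pass, with the same counts adjusted over the list alone. Heat shock factor 1, Os05g0530400, rose by 2.52 ± 0.079 by its brightest probe, with 1.54 as its lowest probe value, and Os01g0749300 by 1.97 ± 0.040; the list had an adjusted p of 0.00174 in limma's camera and an adjusted p of 0.582 with an estimated correlation. Among 144 heat shock protein and DnaJ chaperone genes, 39 rose, 35 fell and 70 did not pass, with the same counts adjusted over the list alone, with the DnaJ-like gene Os03g0776900 at 3.66 ± 0.073 and an adjusted p of 0.679 in limma's camera. For 62 NAC genes, 33 rose, 13 fell and 16 did not pass, against 34 and 14 that passed adjusted over the list alone. Beside Os01g0816100, Os05g0194500 rose by 3.95 ± 0.090, and Os05g0563000 fell to -1.22 ± 0.040. The NAC list had an adjusted p of 0.0416 in limma's camera, an adjusted p of 0.642 with an estimated correlation and one of 0.240 with median centring in place of loess, and the call was also lost under 4 other settings. Of 51 genes in the AP2/ERF list, 25 rose, 10 fell and 16 did not pass, with the same counts adjusted over the list alone. The dehydration-responsive element binding gene Os08g0545400 rose by 4.39 ± 0.15 and another such gene, Os04g0549700, fell to -0.91 ± 0.038. The highest member, the coactivator gene Os06g0592500, is by its description no AP2/ERF factor, and without it and 9 other members of unrelated description, a choice made after seeing the data, 22 of 41 rose and 8 fell. The full AP2/ERF list had an adjusted p of 0.0416 in limma's camera, an adjusted p of 0.689 with an estimated correlation and one of 0.0523 where genes had to be well above background in both channels. Its pattern missed 32 tested genes described as pathogenesis-related transcriptional factor and ERF, of which 13 rose and 6 fell. Of 145 MYB genes, 53 rose, 28 fell and 64 did not pass, against 55 and 28 that passed adjusted over the list alone, with MYBS3, Os05g0442400, at 4.48 ± 0.44, the GAMYB-binding protein gene Os06g0507300, not a MYB factor itself, at 4.12 ± 0.044 and the Myb-like gene Os03g0720800 at -1.38 ± 0.087. This list did not pass in limma's camera (adjusted p of 0.211).

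Signalling genes also rose more often than they fell, though their lists did not pass. Of 76 receptor-like kinase genes, 36 rose, 17 fell and 23 did not pass, with the same counts adjusted over the list alone. Os07g0550400 rose by 2.62 ± 0.22, and Os08g0374600 rose by 2.86 ± 0.18 by its brightest probe, with 0.36 as its lowest probe value; the list had an adjusted p of 0.144 in limma's camera. Among 32 MAP kinase cascade genes, 13 rose, 7 fell and 12 did not pass, with the same counts adjusted over the list alone. The MAP kinase-like gene Os07g0584100 rose by 2.19 ± 0.12, MAP kinase 1, Os03g0285800, rose by 1.78 ± 0.079 and Os05g0576800 fell to -0.60 ± 0.055 (adjusted p of 0.334 for the list in limma's camera). For 154 calcium sensor and pump genes, 62 rose, 30 fell and 62 did not pass, with the same counts adjusted over the list alone. The highest members, Os11g0506800 at 3.99 ± 0.047 and Os05g0197300 at 3.39 ± 0.093, carry an IQ calmodulin-binding region and are by that description partners of calcium sensors. The full calcium list had an adjusted p of 0.144 in limma's camera. Without calmodulin-binding members, a choice made after seeing the data, 46 of 106 genes rose and 16 fell, with an adjusted p of 0.0333 in limma's camera and an adjusted p of 0.510 with an estimated correlation.

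Among the hormone lists, that of jasmonate genes had the highest share that rose. Of 37 genes of jasmonate synthesis and signalling, 23 rose, 3 fell and 11 did not pass, against 24 and 3 that passed adjusted over the list alone. The oxophytodienoate reductase genes Os06g0216300 and Os06g0215600, whose enzymes act in jasmonate synthesis, rose by 4.32 ± 0.12 and 3.61 ± 0.053, and an allene oxide synthase gene, Os02g0218800, fell to -0.50 ± 0.068. The list median was 0.56, with an adjusted p of 0.000161 in limma's camera and an adjusted p of 0.582 with an estimated correlation. Among 90 genes of abscisic acid response, late embryogenesis abundant (LEA) proteins and dehydrins, 44 rose, 13 fell and 33 did not pass, against 44 and 14 that passed adjusted over the list alone. The LEA gene Os01g0314800 rose by 2.66 ± 0.091 and an abscisic acid response element binding factor gene, Os07g0686100, fell to -1.17 ± 0.043. An adjusted p of 0.0118 for this list in limma's camera stood against an adjusted p of 0.642 with an estimated correlation. For 22 ethylene genes, 8 rose, 5 fell and 9 did not pass, against 10 and 5 that passed adjusted over the list alone. The aminocyclopropane-carboxylate oxidase genes Os05g0149400 and Os11g0186900, which catalyse the last step of ethylene synthesis, rose by 2.70 ± 0.21 and 2.16 ± 0.079, and an ethylene receptor gene, Os02g0820900, fell to -0.84 ± 0.068, with an adjusted p of 0.483 for the list in limma's camera. Of 83 genes in the auxin list, 25 rose, 19 fell and 39 did not pass, with the same counts adjusted over the list alone. The auxin efflux carrier gene Os09g0554300 rose by 2.64 ± 0.11 and the SAUR gene Os02g0643800 by 1.52 ± 0.092, beside the fall of ILL5 (adjusted p of 0.889 for the list in limma's camera). The auxin pattern missed 14 tested genes described as AUX/IAA, of which 10 rose and 1 fell, with a median of 0.71. Of these, 4 were at least 2-fold higher (adjusted p of 0.194 in a one-sided Fisher's exact test, chosen after seeing the data).

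Cell wall genes fell more often than they rose. Of 115 genes of cell wall loosening and synthesis, 17 rose, 38 fell and 60 did not pass, with the same counts adjusted over the list alone. The beta-expansin gene Os03g0102700 fell to -1.51 ± 0.23 and expansin EXPA3, Os01g0249100, to -1.24 ± 0.18, both lost as calls without replicate 2, while a pectin methylesterase gene, Os01g0311800, rose by 1.52 ± 0.13 and another beta-expansin gene, Os02g0658800, rose by 1.31 ± 0.15. The cell wall list had an adjusted p of 0.0416 in limma's camera and an adjusted p of 0.582 with an estimated correlation, and the call was also lost under 6 other settings. Among 72 phenylpropanoid and lignin genes, 21 rose, 12 fell and 39 did not pass, against 19 and 12 that passed adjusted over the list alone. A deoxychalcone synthase gene, Os04g0447700, rose by 4.08 ± 0.12, a cinnamoyl-CoA reductase gene, Os08g0277200, rose by 3.85 ± 0.38 and a laccase gene, Os11g0708100, fell to -0.87 ± 0.084, with an adjusted p of 0.595 for the list in limma's camera. For 94 pathogenesis-related genes, 38 rose, 14 fell and 42 did not pass, against 39 and 14 that passed adjusted over the list alone. The chitinase genes Os11g0702100 and Os10g0543400 rose by 3.10 ± 0.21 and 2.77 ± 0.14, in contrast to PR-1a (adjusted p of 0.0765 for the list in limma's camera). The list of diterpenoid phytoalexin synthesis held 1 tested gene, the copalyl diphosphate synthase gene Os04g0178300, with a log2 ratio of -1.44 ± 0.42 (probes between -1.59 and -0.79). Its log2 ratios on the 3 arrays were -2.05, -2.02 and -0.26. It did not pass over all genes, with an adjusted p of 0.0524 in the limma fit. It passed over the list alone, where with 1 gene no adjustment is made. In the list of 54 genes of fermentation and low-oxygen response, 21 rose, 6 fell and 27 did not pass, with the same counts adjusted over the list alone. Non-symbiotic hemoglobin 2, Os03g0226200, rose by 4.21 ± 0.11 and pyruvate decarboxylase 1, Os05g0469600, which opens the path to ethanol, rose by 3.38 ± 0.31 by its brightest probe, with 1.78 as its lowest probe value. The full list had an adjusted p of 0.203 in limma's camera. Without alcohol dehydrogenases of other types, a choice made after seeing the data, 15 of 31 rose and 0 fell, with an adjusted p of 0.0128 in limma's camera and an adjusted p of 0.601 with an estimated correlation.

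Of 297 ribosomal protein genes, 13 rose, 121 fell and 163 did not pass, against 12 and 116 that passed adjusted over the list alone, and none reached 2-fold. The ribosomal protein L10 family genes Os12g0105200 and Os11g0105400 fell to -0.95 ± 0.071 and -0.82 ± 0.069, and a gene described as 60S ribosomal protein L10, Os05g0169100, rose by 0.76 ± 0.060. The list median of -0.12 had an adjusted p of 7.78e-07 in limma's camera and an adjusted p of 0.582 with an estimated correlation. With median centring in place of loess the ribosomal median turned to 0.15, with an adjusted p of 0.0826 in limma's camera, so the direction rests on the normalization. Of 54 proteasome genes, 10 rose, 9 fell and 35 did not pass, against 7 and 5 that passed adjusted over the list alone, with a median of 0.0029, camera direction down and an adjusted p of 0.763 in limma; median centring gave a median of 0.28 and an adjusted p of 0.000819 in limma's camera. The proteasome genes Os08g0529100 and Os06g0176000 had log2 ratios of 0.43 ± 0.055 and -0.42 ± 0.049, the call of the former being lost with no replicate block. Among 122 vesicle trafficking genes, 39 rose, 23 fell and 60 did not pass, with the same counts adjusted over the list alone, and the exocyst subunit gene Os11g0649900 rose by 2.70 ± 0.088 while the Ras-related gene Os01g0750000 fell to -0.71 ± 0.056, with an adjusted p of 0.496 for the list in limma's camera. The transcript of Os11g0649900 is also assigned to another locus, so the copies cannot be separated.

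The list of core histones, DNA replication and cyclins, fixed as markers of dividing cells, held 384 tested genes, of which 100 rose, 95 fell and 189 did not pass, against 99 and 95 that passed adjusted over the list alone. Its highest members, Os09g0342000 at 4.62 ± 0.073 and Os09g0344400 at 4.10 ± 0.043, are cyclin-like F-box genes, a family of protein degradation, while the cyclin genes Os07g0556000 and Os12g0588800 fell to -1.46 ± 0.14 and -1.21 ± 0.063. The full list had an adjusted p of 0.546 in limma's camera. Without the 291 F-box members, a choice made after seeing the data, 9 of 93 genes rose and 53 fell, with a median of -0.24. That list had an adjusted p of 2.38e-06 in limma's camera, an adjusted p of 0.510 with an estimated correlation and one of 0.00347 with median centring, the direction being down in each. Of 67 photosynthesis genes, fixed as markers of green shoot cells, 17 rose, 14 fell and 36 did not pass, against 14 and 12 that passed adjusted over the list alone. A chlorophyll a-b binding protein gene, Os09g0346500, rose by 2.43 ± 0.46, with probes between 0.77 and 2.51 and a call lost without replicate 1, and the plastocyanin-like gene Os08g0482600 rose by 3.65 ± 0.11; the list had an adjusted p of 0.500 in limma's camera. Without plastocyanin-like members, a choice made after seeing the data, 6 of 36 rose and 4 fell. The 3 secondary wall cellulose synthase genes, markers of xylem, all fell, also adjusted over the list alone, with log2 ratios of -0.78 ± 0.041 for Os10g0467800, -0.53 ± 0.051 for Os01g0750300 and -0.23 ± 0.063 for Os09g0422500, the last a call lost under 8 of the alternative settings. In the list of 11 root hair, endodermis and Casparian strip genes, 6 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. The named members are all GRAS-type genes described as Scarecrow-like: Os11g0705200 rose by 2.04 ± 0.13, Os11g0705800 by 2.01 ± 0.14 and Os01g0948200 by 0.76 ± 0.11, a call lost without replicate 2, and Os07g0567700 fell to -0.53 ± 0.068. The root list had an adjusted p of 0.0416 in limma's camera and an adjusted p of 0.582 with an estimated correlation, and the call was also lost under 3 other settings. A description as Scarecrow-like does not place a gene in root hair, endodermis or Casparian strip. The root list was not tested without such members, so its shift cannot be read as one of these cell types.

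**Figure D3:**
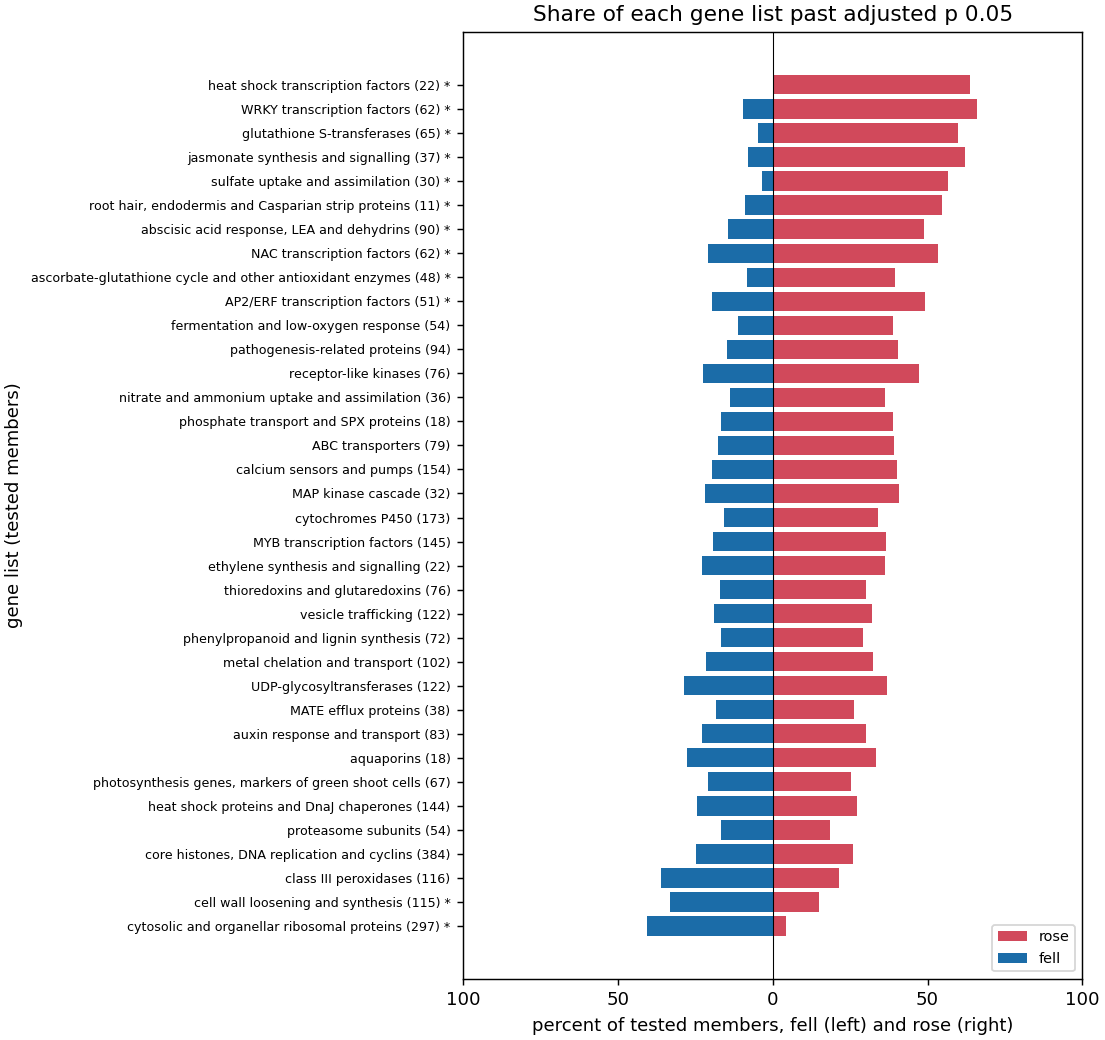
Percent of the tested members of each of 36 gene lists that rose (right) or fell (left) at an adjusted p under 0.05 in the limma fit, with the number of tested members in brackets and a star on the 12 lists past an adjusted p of 0.05 in camera with the preset correlation. The heat shock factor list has no member that fell, and the ribosomal protein list, whose direction turns with median centring, has the highest share that fell.

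Of the 36 lists tested, 12 passed an adjusted p of 0.05 in limma's camera with the preset correlation, 10 of them up and 2 down. With an estimated correlation 0 lists passed, the lowest adjusted p in limma's camera being 0.582, and 1 list had an unadjusted p under 0.05. By limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 31 lists passed.

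Some genes were well above background in only 1 channel, where the ratio rests on a dim signal. In the Cr(VI) channel alone this held for 82 features, 74 of them called higher. The largest value among genes of described function was 18.3-fold higher for the carboxyl methyltransferase gene Os02g0719600. Its log2 ratios on the 3 arrays were 4.01, 4.85 and 3.73. Next were 6.67-fold for the esterase/lipase gene Os07g0526600 and 5.65-fold for CYP51, Os05g0211100, a P450 of sterol synthesis. In the water channel alone it held for 3 features, all called lower, of which the sulfotransferase gene Os08g0515100 was 1.63-fold lower. These 4 genes had adjusted p-values between 0.000714 and 0.00252 in the limma fit. In each of them the probe's own dim signal set the bound, so the fold given is the fitted ratio and not a minimum.

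The 3 arrays resembled one another to different degrees. Across tested features, which are not independent replicates, Pearson's r of the log2 ratios was 0.943 between replicates 1 and 2, 0.870 between 1 and 3 and 0.884 between 2 and 3. Replicates 1 and 2 shared a slide and a scan, and replicate 3 was alone on another slide and scan, so slide, scan and biological replicate cannot be told apart for replicate 3. The 10 external control RNAs, which are added to the samples and are not of rice, had mean log2 ratios from -2.95 to 2.51 after the normalization of the rice spots. The amounts of each RNA added to each channel were not used here, so this range is no measure of error. Averaged over the 10 RNAs, the log2 ratio was -0.15 on replicate 1, 0.033 on replicate 2 and -0.76 on replicate 3. Once each array was centred on that average, the highest SD of a control RNA over the arrays dropped from 0.497 to 0.0913.

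**Figure D4:**
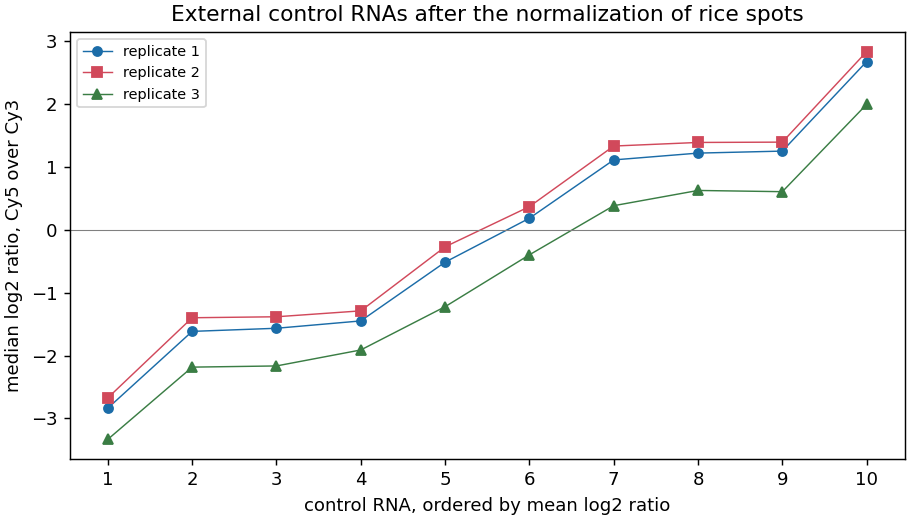
Median log2 ratio of Cy5 over Cy3 for each of the 10 external control RNAs, ordered by their mean ratio, with 1 line per array. The line of replicate 3 runs below the others throughout, with an average of -0.76 against -0.15 and 0.033.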

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

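The alignment on control RNAs, the trimmed lists, the count of locus genes alone and the pooled slide correlation were chosen after seeing the data. Of 2906 values of the 162 named genes under the alternatives, 2791 kept direction and call, 111 kept direction and lost the call, 4 gained it and 0 reversed, and 116 genes kept both everywhere. Against 7008 higher, 5781 lower, 1805 at least 2-fold higher and 276 at least 2-fold lower as reported, the 2-fold higher count ranged from 1545 to 2185, apart from counting every probe as a feature, which gave 2544. Agilent's processed signals gave 473 features at least 2-fold lower, and the authors' values, which are not centred, called 9319 lower and 733 at least 2-fold lower. Against a minimum fold of 1.5, limma's treat called 1640 higher and 210 lower, since it asks for a larger change. Aligning the arrays to one another on the external control RNAs, with the mean control ratio of the 3 arrays kept, left 2617 higher and 738 lower; scaling to the controls' own level was not run. That alignment moves the rice ratios of each array, already normalized by loess, by the array's control average. The differences between arrays in that average, the largest being that of replicate 3, thereby enter every gene's spread. With it, 1805 of the 2-fold higher and 276 of the 2-fold lower calls were shared with the counts reported. Leaving out each replicate in turn gave 3373 to 7310 higher, 1507 to 6018 lower, 1545 to 1851 at least 2-fold higher and 166 to 373 at least 2-fold lower features, the lowest always without replicate 2 and the highest without replicate 3, with fewer samples in each fit. Treating both channels as 6 single samples with no replicate block gave 5678 higher, 3986 lower, 1786 at least 2-fold higher and 272 at least 2-fold lower. The planned random block by slide was not run, as duplicateCorrelation gave an estimate for 0 features with 3 arrays; a correlation of 0.572 pooled by moments gave 5494 higher and 4051 lower. The number of lists passed was 0 in limma's camera with an estimated correlation (1 at an unadjusted p under 0.05), 31 by fry and 9 to 15 otherwise. Of 756 list values, 29 lost the call, 29 gained it and 3 reversed. The ribosomal list reversed with median centring (adjusted p = 0.0826 in limma's camera), as did the proteasome list (0.000819), and the cause was not tested. The other reversal was the full cell cycle list, with a mean log2 ratio of 0.0837, by fry (adjusted p = 0.0121). Fry asks whether a list moves on balance from 0, while camera compares it with other genes and had not called it (adjusted p of 0.546). The 5056 locus genes left out by the filter on dim signals or by an outlier spot have no value here.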

Other observations

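The tests of gene families, of compressed ratios and of slide or scan below were chosen after the results were seen. Outside the fixed lists, 149 families of at least 10 tested genes with the same description were set against 11888 features with a described function outside those lists, of which 771 were at least 2-fold higher and 104 at least 2-fold lower (one-sided Fisher's exact tests, Benjamini-Hochberg adjusted over both directions). Protein kinase genes were at least 2-fold higher in 66 of 474 cases (adjusted p = 6.70e-07), and 8 of 17 genes of the VQ domain family, whose proteins bind WRKY factors, were (adjusted p = 0.000647). The VQ genes Os06g0666400 and Os02g0173200 had log2 ratios of 3.17 ± 0.13 and 2.82 ± 0.065 in the limma fit. Transferase family genes (12 of 62), universal stress protein genes (6 of 18) and AAA ATPase genes (8 of 32) were also over-represented, each with an adjusted p of 0.0390. The universal stress protein gene Os03g0305400 stood at 3.60 ± 0.51. Sulfotransferase genes went the other way, with 11 of 17 lower and 4 at least 2-fold lower (adjusted p = 0.00120), among them Os11g0505300 at -1.54 ± 0.12. Fisher's test takes genes as independent, and no correlation between the genes of a family was allowed for. The fixed lists lost their calls in camera once one was estimated, in a test of little power with 3 arrays. These family medians kept their signs with median centring and with Agilent's processed signals. Of 218 miRNA precursor probes tested, 22 were higher and 60 lower, with 0 and 1 at least 2-fold.

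Features at least 2-fold higher lay next to each other in the order of their locus identifiers, which stood in for positions that the files do not give, more often than in random orders. Of 24621 neighbouring pairs of tested loci on the same chromosome, 265 were both at least 2-fold higher, against a highest value of 174 and a mean of 131.7 in 1000 random orders. The hypothesis that probes shared among tandem copies account for this was tested by leaving out pairs whose probes share a run of 20 bases or whose descriptions are alike. That left 196 pairs, above the highest value of 167 in random orders, so shared probes are not the whole of it; diverged relatives with other descriptions were not excluded. The longest run had 7 loci on chromosome 2, from Os02g0559800 at 6.05 ± 0.073 to Os02g0561900 at 3.09 ± 0.049, but 5 of these loci share 1 transcript sequence and the last shares its own with other loci, so the run cannot be counted as 7 separate signals. Another run held 6 cytochrome P450 genes on chromosome 1, from Os01g0627400 to Os01g0628000, and another on chromosome 10 held 4 glutathione S-transferase genes beside a P450 gene, with Os10g0525600 at 4.55 ± 0.30.

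Calls under 1.5-fold made up 66.6% of all calls, with the dyes in one orientation. If they came from a dye effect tied to the probe, another probe of the same gene would agree in sign by chance only. Of 1596 such genes with another probe that shares no run of 20 bases, 84.96% had the same sign on it (exact 95% interval 83.1% to 86.7%), against 98.0% of 348 genes at 1.5- to 2-fold and 99.0% of 314 at 2-fold or more. The log2 ratio followed the G content of the probe little, with Spearman's rho of -0.0447 across features. Both values argue against a probe's own sequence as the whole source of the small calls, and a dye effect shared by all probes of a transcript stays open without a dye swap.

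Replicate 3 stood apart, with r of 0.870 and 0.884 with the other arrays and an array weight of 0.396 against 1.12 and 2.25. For compressed ratios on that array, the slope of its control RNA ratios on the mean of the others was 0.967 (SE 0.0158), too close to the bound of 0.95 to decide. Among 1221 features at a log2 ratio of at least 1.5 on replicate 2, the median on replicate 3 was 1.097 times that on replicate 1 (bootstrap 95% interval 1.07 to 1.12), and among 898 features picked on replicate 1 it was 0.940 times that on replicate 2 (0.919 to 0.963). With 0.919 as the lowest end of an interval, these values argue against a strong compression of rises. A slight compression of rises stays open. For features picked at -1.5 or less the same ratios were 0.570 and 0.358. The 74 features picked at -1.5 or less on replicate 3 had medians of -1.05 on replicate 1 and -1.31 on replicate 2. Falls were thus also smaller on the other arrays when picked on replicate 3, and these ratios do not show compression on that array alone. Slide and scan changed together with the biological replicate, so these cannot be told apart from a difference between the seedlings (0.870 is the lower correlation).

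Rises reached further than falls, with 6.54 times as many 2-fold higher as lower calls. A floor on measurable falls may add to this: among 16624 features whose water signal left room for an 8-fold fall, 986 were at least 2-fold higher and 234 lower, a ratio of 4.21. The ratio was 8.05 with median centring in place of loess, while Agilent's processed signals gave 2185 and 473 such calls and the authors' deposited values, whose median is -0.13, 1898 and 733. The size of the excess thus depends on the signals and their centring; neither the floor nor the loess curve accounts for the whole of it, and a response to Cr(VI) that is mainly induction remains as a hypothesis, found and tested on the same data. A change in total mRNA per root was not tested.

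Turning the sign of 1 array gives 4 splits, too few for a share under 0.05: the real split had 7008, 5781, 1805 and 276 calls in limma and the highest of the others 0 each, with 11 to 290 features at an unadjusted p under 0.05, and 1 of 4 splits reached the real counts.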
